A study of Mus musculus with 4 samples.

How the data were processed

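Gene expression was measured in mouse synovial fibroblasts with a 1-colour Affymetrix GeneChip. Per the labels, the cells came from knee joints of male DBA/1J mice without arthritis, were passaged, and were kept in low-serum medium. Per the labels, dishes received vehicle, IL-1β at 5 ng/ml, IL-1β with 1 µM indomethacin, or IL-1β with 1 µM indomethacin and 1 µM iloprost, for 6 h. Indomethacin blocks the cyclooxygenases and with them the synthesis of all prostanoids, and iloprost is a stable analogue of prostacyclin. Each of the 4 groups has 1 array. A dish with IL-1β and iloprost but no indomethacin is not analysed here.

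The deposited values are intensity values, 1 linear signal per probe set and array, never negative. Per the labels, RNA was labelled and hybridised by standard Affymetrix procedures. The software that summarised the probes, its background correction and its scaling are not given in the sources used here. The deposited arrays were not scaled to a common mean or median. Their 2% trimmed means were 129.3 (vehicle), 156.8 (IL-1β), 138.9 (IL-1β and indomethacin) and 136.3 (with iloprost), and their medians were 35.2, 40.6, 36.1 and 39.4. The number of arrays limits the precision. All columns of the value table were used.

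Probe sets were named through the platform's annotation table, which can be old, and symbols were checked by gene number against the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. The RefSeq table was used for names only, so no coordinates are given. Of 22690 probe sets, 21084 are in the annotation table and 1606 are unnamed here. Another 691 name several genes and were not used. The remaining 20380 probe sets name 12393 genes. The 64 control probe sets were left out of the gene values, including 13 that name 1 gene. This exclusion was made after a first look at the results and removed 1 gene, Gapdh. No probe set with that gene alone was left.

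Signals below a floor of 37.6, the 50th percentile of all values on the 4 arrays, were set to the floor, and log2 was taken. A gene took its probe set with the highest mean log2 signal. A gene at the floor on both arrays of a comparison has no ratio there. With 1 array at the floor the ratio is a bound, written as at least or at most. Genes are counted as higher or lower at a 2-fold difference.

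The arrays differ in brightness as a whole, by up to 0.23 on the log2 scale for the median gene. Counts of genes were planned on the scale as deposited and are given so. They are also given relative to the median gene of the comparison, since the split of higher against lower genes depends on this choice. Ratios of single genes and of gene lists are given relative to the median gene, which stands for the median log2 signal on an array of the 6226 genes above the floor on every array. This was decided after the brightness of the arrays was seen. As deposited, each such ratio and list median is shifted by 0.23 for IL-1β against vehicle, -0.15 for indomethacin, 0.01 for iloprost against indomethacin and -0.14 for iloprost against IL-1β alone.

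With 1 array per group there is no replicate spread, no test between groups and no p-value for any gene or list. All differences describe these 4 dishes. As a measure of measurement noise within an array, log2 ratios were compared between probe sets of the same gene. Their SD per probe set was 0.21 for IL-1β against vehicle, 0.19 for indomethacin, 0.20 for iloprost against indomethacin and 0.20 for iloprost against IL-1β alone. This noise does not include differences between dishes.

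Before the data were examined, 29 gene lists with 550 entries were fixed, and 497 entries had a usable probe set. The other 53 are not analysed here. A list is described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile is a description of these arrays. Across lists and comparisons, 104 percentiles were computed, of which 26 lay below 2.5 and 20 above 97.5.

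The genes named in the text were chosen by a rule fixed before the data were examined. For each comparison it takes the 10 highest and 10 lowest log2 ratios among genes above the floor on both arrays and at or above a signal of 113.2, the 70th percentile, on the brighter array. It adds up to 6 genes per direction that are at the floor on 1 array and at least 4-fold above it on the other. It also takes the 2 to 4 list members with the largest ratios, the receptors and enzymes of the drugs and of IL-1β, and the 15 genes with the clearest opposite response to indomethacin and iloprost. The probe sets of named genes that differed by over 1.5-fold and were above the floor on both arrays were compared. No other probe set of such a gene above the floor went the other way by over 1.5-fold, relative to the median gene. Genes with smaller ratios or bounds were not checked in this way. The cyclooxygenase gene Ptgs1 is not analysed here. Some list members outside the rule are also named, chosen after their values were seen.

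The indomethacin ratio and the iloprost ratio share an array, whose noise alone makes them go opposite ways. The count of such genes was therefore set beside 1000 simulated sets of unchanged arrays, with noise taken in 10 brightness bins from the indomethacin ratio, and in an added version from the wider iloprost ratio. The IL-1β ratio and the indomethacin ratio share the IL-1β array in the same way. The IL-1β ratio and the iloprost ratio share no array.

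The steps were tested on simulated data for IL-1β against vehicle, with 6951 genes, noise of 0.2 per array and an added shift of 0.2. Of 50 genes changed 1.5-fold, 1 was counted at the 2-fold threshold. Of 50 changed 2-fold, 23 were counted, of 50 changed 3-fold, 50, and of 50 changed 4-fold, 49. None of 6751 unchanged genes was counted. Changed genes were drawn only from those with a mean signal over 2-fold above the floor, and all genes had the same noise. So these numbers do not cover changed genes near the floor or noise that depends on brightness. The shift was recovered as 0.20, and 1 of 100 unchanged lists lay outside the middle 95%.

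Alternatives fixed before the data were examined were floors at the 30th and 65th percentile, a pseudocount in place of the floor, no floor together with no filter on low values, scaling by trimmed mean or median, quantile and loess normalization, the mean over probe sets, leaving out cross-hybridising probe sets, and thresholds of 1.5-fold and 3-fold, with 2-fold for the combined pattern. Ratios as deposited, the wider simulated noise and the combined pattern relative to the median gene were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.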

Results

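RNA from 4 dishes of mouse synovial fibroblasts was measured on 4 arrays, 1 for each treatment. Synovial fibroblasts line the joint and respond to IL-1β, a cytokine of joint inflammation. The dishes received vehicle, IL-1β, IL-1β with indomethacin, or IL-1β with indomethacin and iloprost for 6 h. Per the series title, the study asked how prostacyclin signalling acts on cells activated by IL-1β. Between 48.8% and 51.2% of probe sets were above the floor on each array. The log2 signals of 6226 genes above the floor on every array correlated across genes between arrays with r from 0.94 to 0.99. There were no replicates, so no value below has an error between dishes, and log2 ratios are relative to the median gene.

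All 4 dishes held fibroblast RNA and RNA of macrophage marker genes. The collagen gene Col1a2 had signals from 5510 to 5698 and the intermediate filament gene Vim from 5539 to 6052. The macrophage lysozyme gene Lyz2 had signals from 5342 to 6247, and the colony-stimulating factor receptor gene Csf1r from 3998 to 4731. Of 24 macrophage markers, 24 were measured with IL-1β against vehicle. Of 13 endothelial markers 1 was measured, of 12 chondrocyte markers 2, of 11 adipocyte markers 3, and of 12 lymphocyte markers 0. The added control transcripts, 18 probe sets, were brighter on the IL-1β array than on the vehicle array by a median log2 of 0.22, and were at -0.05 with indomethacin and -0.21 with iloprost against vehicle.

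IL-1β was compared with vehicle. Il6, an inflammatory cytokine, had a signal of 312 with vehicle and 4757 with IL-1β, a log2 ratio of 3.70. Ptgs2, the inducible cyclooxygenase, stood at 2.83, the neutrophil chemokine gene Cxcl5 at 2.60, the iron-binding lipocalin gene Lcn2 at 2.87 and Zc3h12a, an RNase that degrades cytokine transcripts, at 3.15. Penk, which encodes enkephalin, and Inhba, a subunit of activin, were both at 3.03. Procr, the protein C receptor, was at 3.01, Uap1, an enzyme that makes UDP-N-acetylglucosamine, at 2.85, and Ccl20 at 2.75. Genes at the floor with vehicle were higher by at least 4.35 for the nuclear receptor Nr4a1, 3.81 for Lif, 3.71 for Ereg, 3.21 for Serpinb2, 2.99 for Tslp and 2.91 for the stromelysin Mmp10. The lowest ratios were -1.88 for the interferon-induced chemokine Cxcl9, -1.74 for the Wnt enhancer Rspo2, -1.37 for tissue factor F3, -1.33 for Casp12, -1.30 for Ddit3, -1.25 for the clock output gene Dbp and -1.18 for Mx1. Within the same limit, Clec2d, Rasa3 and Ctps2 followed at -1.14, -1.12 and -1.10.

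Cytokines as a list had a median of 1.92 with IL-1β, at percentile 100 of random lists. Of 17 measured members 11 were at least 2-fold higher and 0 lower, among them Il1b at 1.92 and the alarmin Il33 at 2.02. Hyaluronan genes had a median of 0.82, at percentile 100, with 3 of 8 at least 2-fold higher, including the precursor enzyme Ugdh at 1.62 and the synthase Has1 at a bound of at least 1.51. Targets of cAMP and CREB had a median of 0.71, at percentile 100, with 8 of 18 higher, including Crem at 1.55 and the phosphodiesterase Pde4b at 1.14. Matrix proteases had a median of 0.59, at percentile 100, with 5 of 19 higher, including the aggrecanase Adamts4 at 2.55 and the stromelysin Mmp3 at 1.79. Bone and Wnt/BMP regulators had a median of 0.43, at percentile 99.99, with 4 of 11 higher and 1 lower, among them Tnfsf11, which encodes RANKL, at a bound of at least 2.17. Of these 11 values 5 are bounds, and with the floor at the 65th percentile the median of the bone and Wnt/BMP regulators was -0.0316. Genes of glycolysis and hypoxia had a median of 0.24, at percentile 99.95, with 3 of 18 higher, including Ndrg1 at 1.26. As deposited, the medians of bone and Wnt/BMP regulators and of glycolysis and hypoxia were 0.66 and 0.47.

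Interferon-response genes had a median of -0.47 with IL-1β, at percentile 0, with 21 of 23 below the median gene and 2 at least 2-fold lower, Mx1 and Mx2 (-1.06). MHC class I and antigen presentation genes had a median of -0.31, at percentile 0, with 0 of 10 past 2-fold. This list shares Tap1, Psmb8 and Psmb9 with the interferon list. Chemokines were mixed, with a median of -0.02, 4 of 20 higher, among them Cxcl1 at 2.30, and 1 lower. NF-κB genes had a median of 0.08, with 2 of 23 higher and 1 lower, and prostanoid genes one of 0.16, with 2 of 13 higher. Of the receptors and enzymes, the IL-1 receptor gene Il1r1 was at 0.79, prostaglandin E synthase Ptges at 0.86, prostacyclin synthase Ptgis at 0.40 and the prostacyclin receptor Ptgir at -0.15. Macrophage markers had a median of -0.11 (percentile 0.43), matrix structural genes -0.09 (percentile 0.53) and contractile genes -0.25 (percentile 0.47), with no macrophage or contractile gene past 2-fold. The macrophage and matrix medians turned positive, to 0.12 and 0.14, on the scale as deposited. There the median of interferon response genes was -0.25, that of MHC class I and antigen presentation genes -0.08 and that of contractile and smooth muscle markers -0.02.

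As deposited, 195 of 6957 genes were at least 2-fold higher with IL-1β and 11 lower, so 94.7% of them were higher. Relative to the median gene, which was brighter by 0.23 on the log2 scale, the counts were 120 higher and 39 lower, or 75.5% higher.

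**Figure D1:**
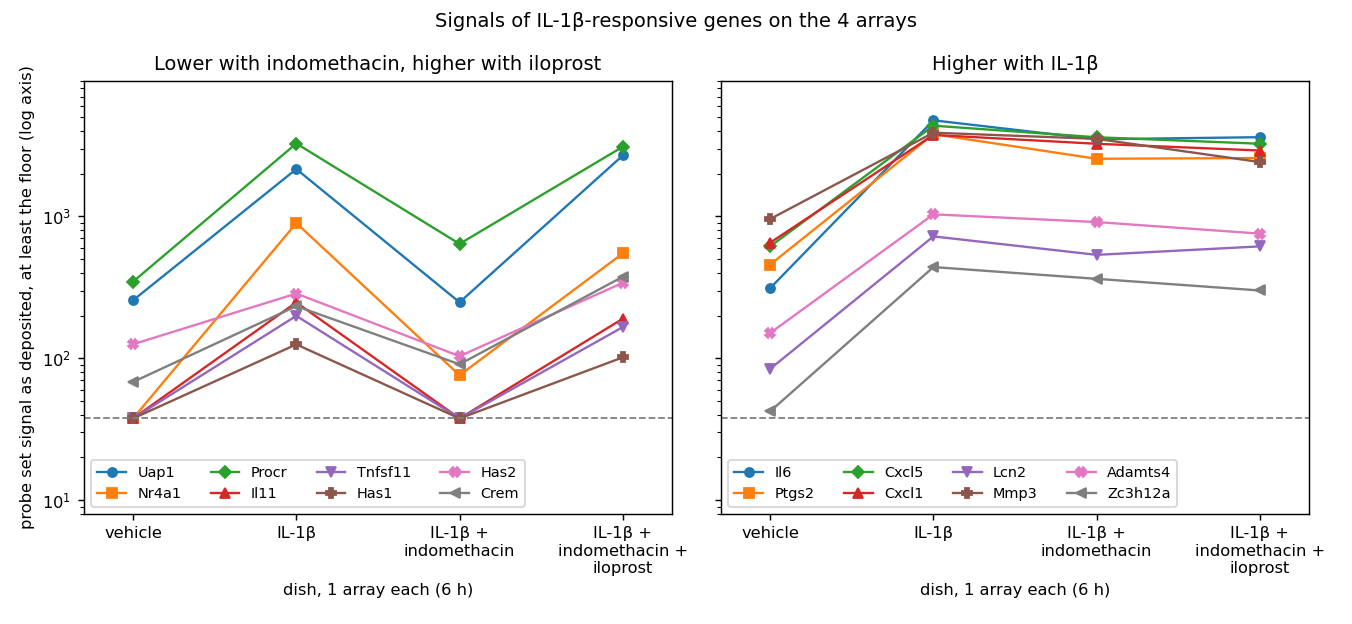
Probe set signals as deposited (log axis) on the 4 arrays for 8 genes lower with indomethacin and higher with iloprost, and for 8 genes higher with IL-1β. Each point is 1 array, signals under the floor of 37.6 are drawn at the floor, shown as a dashed line, and Uap1 stands at 256, 2156, 248 and 2689 from left to right.

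IL-1β with indomethacin was compared with IL-1β alone. This ratio and the IL-1β ratio share the IL-1β array, whose noise alone makes them go opposite ways. Nr4a1 had a log2 ratio of -3.42, Uap1 -2.97, Procr -2.20, the secreted kinase Pkdcc -2.16 and the retinol dehydrogenase Rdh10 -1.97. Kcne4 was at -1.90, Medag at -1.82, thrombomodulin Thbd and the repressor Nfil3 at -1.75, and the stress gene Ddit4 at -1.70. Genes that reached the floor with indomethacin had ratios of at most -2.57 for Il11, -2.31 for Stc1, -2.26 for Tnfsf11, -2.20 for Gem and -1.93 for Nr4a2. Il6, Ptgs2 and Cxcl5 were at -0.30, -0.43 and -0.12. The highest genes were Csf2, the growth factor GM-CSF, at 1.76, the matrix protein Mgp at 1.36, the chemokine Ccl4 at 1.36, Rgs16 at 1.28, Trib2 at 1.24, the prostaglandin E receptor Ptger4 at 1.20, Hmga2 at 1.19, the chemokine Ccl3 at 1.17, Rgs3 at 1.15 and Mocos at 1.13.

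Hyaluronan genes had a median of -0.95 with indomethacin, at percentile 0, with 4 of 8 at least 2-fold lower, including the synthase Has2 at -1.32, Ugdh at -1.13 and the hyaluronan-binding Tnfaip6 at -1.14. Cytokines had a median of -0.42, at percentile 0, with 6 of 17 lower and 1 higher, including Il33 at -1.26, Inhba at -1.17 and Tslp at -1.14. Targets of cAMP and CREB had a median of -0.29, at percentile 0, with 6 of 18 lower, including Pde4b at -1.38 and Crem at -1.21. Genes of glycolysis and hypoxia had a median of -0.18 (percentile 0.05), cholesterol and fatty acid genes -0.14 (percentile 0.85), and glucocorticoid and circadian genes -0.16 (percentile 1.27). As deposited, the medians of glycolysis and hypoxia, cholesterol and fatty acid synthesis, glucocorticoid and circadian genes, and cAMP and CREB targets were -0.33, -0.29, -0.31 and -0.44. Interferon-response genes had a median of 0.25, at percentile 100, with 22 of 23 above the median gene and 0 past 2-fold. As deposited, the median of interferon response genes was 0.10. Chemokines had a median of 0.15, at percentile 100, with 3 of 20 higher, and as deposited the median of chemokines was 0.01. MHC class I and antigen presentation genes had a median of 0.09, at percentile 97.85, which was -0.06 as deposited. NF-κB genes were at 0.01, matrix proteases at 0.00 with Adamts1 at -1.23, macrophage markers at -0.03 and fibroblast genes at -0.02.

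As deposited, 9 of 6928 genes were at least 2-fold higher with indomethacin and 60 lower, so 13.0% were higher. Relative to the median gene, which was dimmer by a log2 of -0.15, the counts were 17 and 46, or 27.0% higher.

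IL-1β with indomethacin and iloprost was compared with IL-1β and indomethacin. The T-cell chemokine gene Cxcl10 had a signal of 3576 without and 105 with iloprost, a log2 ratio of -5.10. The monocyte chemokines Ccl3 and Ccl4 stood at -4.80 and -3.59, the antiviral genes Ifit2, Cmpk2 and Ifit3 at -4.21, -4.15 and -3.61, and Cxcl11 at -3.97. Iigp1, Rsad2 and Ifi209 were at -3.47, -3.21 and -3.11. Genes that reached the floor had ratios of at most -5.63 for Ccl12, -4.20 for Cxcl9, -3.08 for Mx1, -2.69 for Csf2, -2.19 for BC023105 and -2.18 for the RNA sensor Tlr7. The highest genes above the floor were the lectin Cd207 (langerin) at 3.53, Uap1 at 3.43, the neuropeptide Npy at 3.17, Nr4a1 at 2.85, the lipid droplet gene Hilpda at 2.63, Procr at 2.27, Mxi1 and Rdh10 at 2.25, Pkdcc at 2.20 and Medag at 2.06. Genes at the floor without iloprost were higher by at least 5.63 for Cytip, 4.79 for arginase Arg1, 3.75 for Ramp3, 3.16 for Havcr2 (TIM-3), 2.57 for Stc1 and 2.33 for Il11.

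Of 23 interferon-response genes, 22 were at least 2-fold lower with iloprost, and the list median was -1.87, at percentile 0. MHC class I and antigen presentation genes had a median of -1.01, at percentile 0, with 5 of 10 at least 2-fold lower. The lower members were transporters and proteasome subunits, such as Tap1 at -1.86 and Psmb9 at -1.54, which are also on the interferon list. H2-K1, H2-D1 and B2m were at -0.07, -0.14 and -0.15. Chemokines had a median of -0.75, at percentile 0, with 7 of 20 lower and 0 higher, including Ccl5 at -2.11, against -0.16 for Cxcl5 and -0.17 for Cxcl1. NF-κB genes had a median of -0.26, at percentile 0.1, with 4 of 23 lower, including the receptor Cd40 at -2.46 and the adhesion molecule Icam1 at -1.30. Cytokines went both ways, with a median of 0.04, 5 of 17 higher and 5 lower. Tnf was at -2.67, Il18 at -1.52 and Il1b at -1.25, the receptor antagonist Il1rn at 1.08 and Il33 at 1.19, and Il6 at 0.04.

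Hyaluronan genes had a median of 0.90 with iloprost, at percentile 100, with 4 of 8 at least 2-fold higher, including Has2 at 1.71, Ugdh at 1.36 and versican Vcan at 1.34. Targets of cAMP and CREB had a median of 0.56, at percentile 100, with 6 of 18 higher and 1 lower, including Crem at 2.04 and Nfil3 at 1.60, with Egr1 at -1.32. Cholesterol and fatty acid genes had a median of 0.50, at percentile 100, with 3 of 16 higher, the desaturases Scd1 (1.82) and Scd2 (1.31) and the sterol enzyme Sqle (1.13). Genes of glycolysis and hypoxia had a median of 0.42, at percentile 100, with 2 of 18 higher, Ddit4 (1.90) and Bnip3 (1.43), and 1 lower, Adm at -1.05. Bone and Wnt/BMP regulators had a median of 0.31, at percentile 98.17, with 2 of 11 higher and 1 lower. Matrix proteases had a median of -0.06, with Mmp19 at 1.57 and the collagenase Mmp13 at -1.77. Il1r1 was at 1.02, the iloprost receptor gene Ptgir at -1.36 and Ptger4 at -1.79, while prostanoid genes as a list were at 0.07, with 1 of 13 higher and 3 lower.

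Macrophage markers had a median of -0.24 with iloprost, at percentile 0.16, with 1 of 23 at least 2-fold lower, the Fc receptor gene Fcgr1 at -1.46. Below the median gene were 18 of the 23 and above it 5. Adgre1, Cybb and Aif1 were at -0.77, -0.75 and -0.74, Cd68, Csf1r and Lyz2 were at -0.11, -0.07 and -0.09, and Cd14 at 0.62. Fibroblast genes had a median of 0.12 (percentile 92.38), matrix structural genes 0.04 and ribosomal proteins -0.07. Cell cycle genes had a median of 0.33, at percentile 99.63, with 1 of 20 higher and 1 lower, and stress genes one of -0.19, at percentile 1.07. As deposited, 141 of 6982 genes were at least 2-fold higher with iloprost and 221 lower, and relative to the median gene, which differed by 0.01, 138 and 223.

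**Figure D2:**
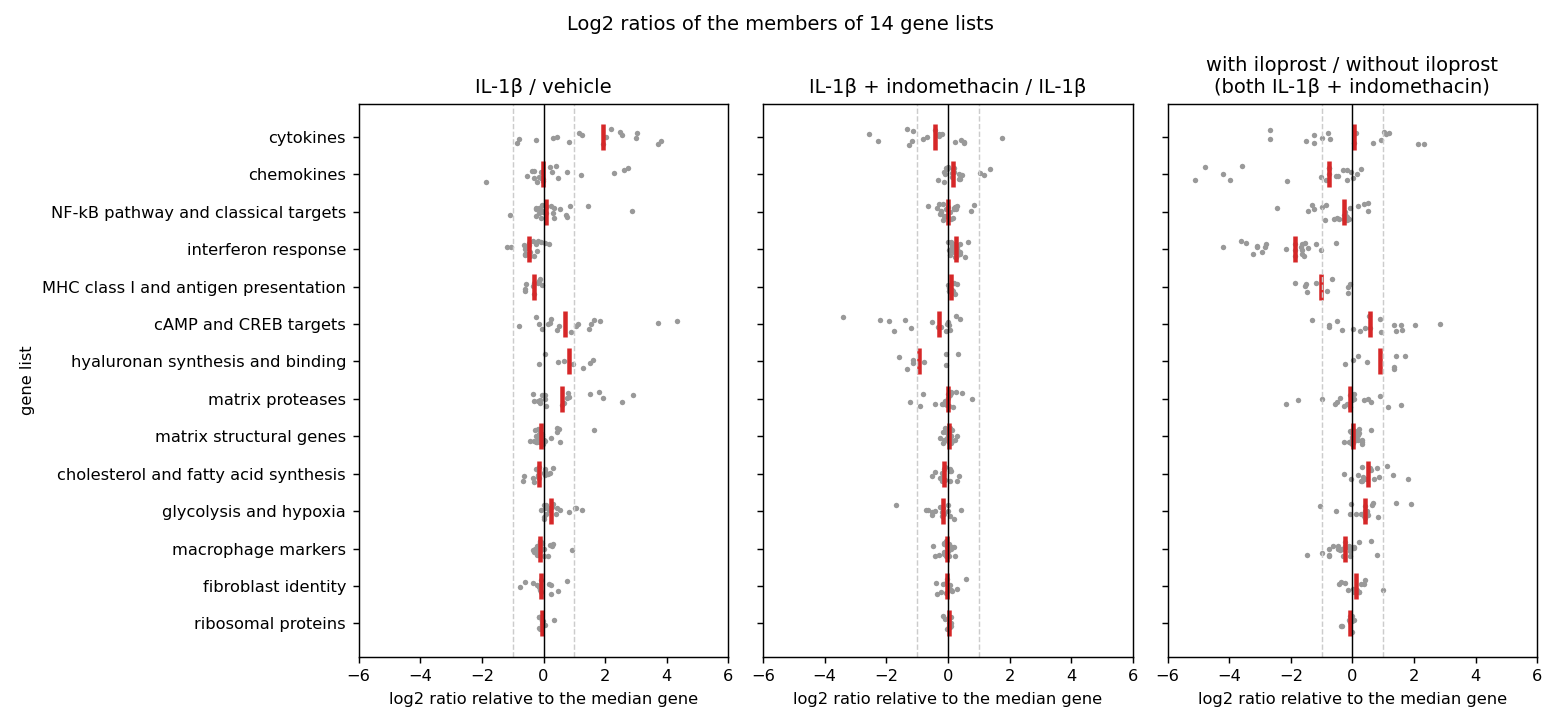
Log2 ratios relative to the median gene of the members of 14 gene lists (grey points, with bounds at their bound) in 3 comparisons, with the list median as a red bar and dashed lines at 2-fold. Interferon-response genes have medians of -0.47, 0.25 and -1.87 from left to right, and hyaluronan genes 0.82, -0.95 and 0.90, and each ratio compares 1 array with 1 array.

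**Figure D3:**
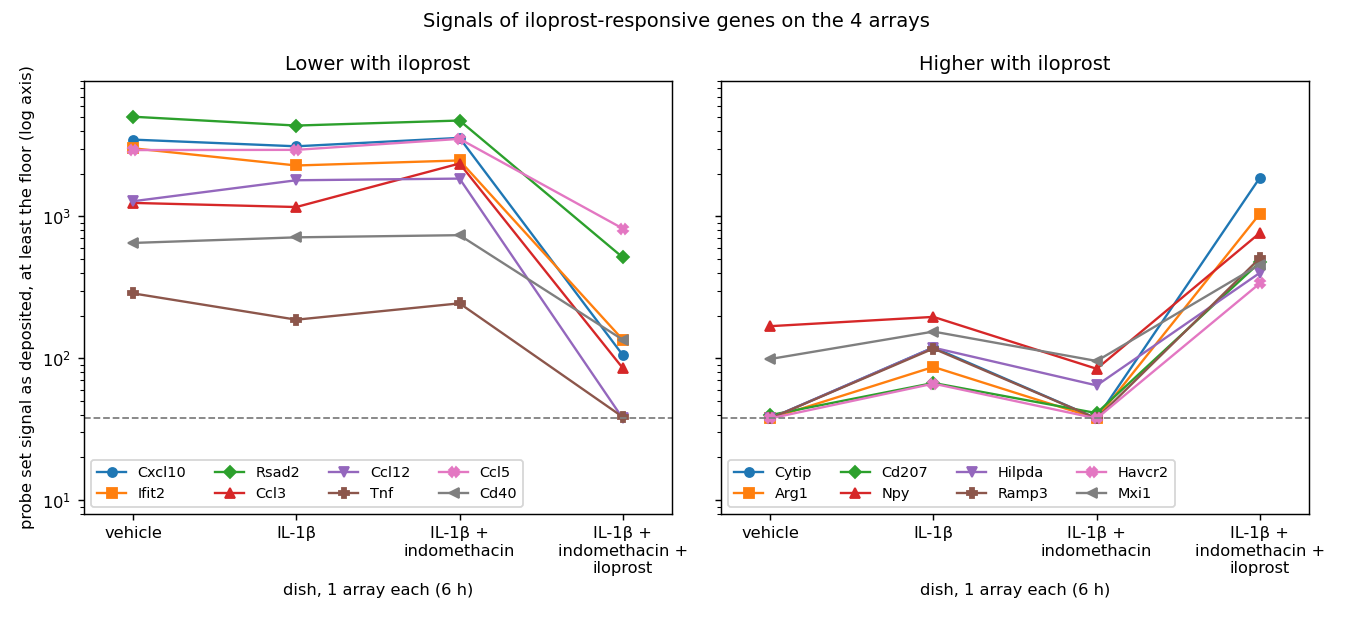
Probe set signals as deposited (log axis) on the 4 arrays for 8 genes lower and 8 genes higher with iloprost, 1 array per point, with signals under the floor of 37.6 drawn at the floor (dashed line). Cxcl10 stands at 3478, 3119, 3576 and 105 from left to right.

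Genes that were lower with indomethacin and higher with iloprost were counted at a 1.5-fold threshold. The 15 genes with the clearest pattern were Uap1, Nr4a1, Il11, Stc1, Procr, Pkdcc, Tnfsf11, Rdh10, Medag, Kcne4, Ddit4, Nfil3, Thbd, Cytip and Ramp3. Uap1 was 256 with vehicle, 2156 with IL-1β, 248 with indomethacin and 2689 with iloprost, and Procr 347, 3264, 640 and 3097. As deposited, 183 of 6817 genes had this pattern, and 66 of them were also at least 2-fold higher with IL-1β. Relative to the median gene, 119 had it, and 49 of them were also higher with IL-1β. Independent lists would share 25.9 and 12.4 genes. Simulated unchanged arrays share the indomethacin array in the same way. They gave a median of 8 and a highest count of 19, and with wider noise 47 and 71. They carried no shift in brightness, so they compare with the counts relative to the median gene only. The opposite pattern, higher with indomethacin and lower with iloprost, held for 33 genes as deposited and 60 relative to the median gene, against highest simulated counts of 20 and, with wider noise, 70. The count of 60 thus lay above the narrower noise and within the wider noise. The wider noise was taken from the iloprost ratio, with a spread across genes of 0.32. It was also given to the indomethacin ratio, whose spread was 0.20. So the simulations cannot decide whether this count is noise. The 60 genes included Csf2, Mgp, Ccl4, Rgs16, Ptger4 and Ccl3.

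Across 6226 genes, the indomethacin and iloprost ratios correlated with r of -0.52, where simulated unchanged arrays gave -0.50, with a covariance of -0.07 against -0.02, or -0.05 with wider noise. The IL-1β and indomethacin ratios, which share the IL-1β array, correlated with r of -0.53, with a covariance of -0.05. This pair was not simulated with its own noise, so the simulated values above cannot decide how much of it is noise. The IL-1β ratio and the iloprost ratio, which share no array, correlated with r of 0.19 and rho of 0.10. Genes are not independent replicates. The 120 genes at least 2-fold higher with IL-1β relative to the median gene had a median iloprost ratio of 0.35, where the middle 95% of random lists ran from -0.05 to 0.09. Of these genes, 53 were at least 1.5-fold higher with iloprost and 15 lower. The 37 genes measured in both comparisons that were at least 2-fold lower with IL-1β had a median iloprost ratio of -0.29, against -0.08 to 0.21.

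IL-1β with both drugs was also compared with IL-1β alone. Several genes that were lower with indomethacin stood close to their IL-1β level with both drugs, such as Procr at 0.06, Pkdcc at 0.04 and Rdh10 at 0.28. The lowest ratios were Cxcl10 at -4.75, Ifit2 at -3.94, Cmpk2 at -3.92, Ccl3 at -3.63, Cxcl11 at -3.60, Ifit3 at -3.27, Iigp1 at -3.07, Ifi209 at -3.02, Rsad2 at -2.95 and Ms4a4c at -2.93. Bounds were at most -5.44 for Ccl12, -3.16 for Cxcl9, -2.54 for Mx1, -2.01 for Tlr7, -1.96 for Slfn8 and -1.94 for BC023105. The highest ratios were 4.12 for Cytip, 3.73 for Arg1, 2.97 for Cd207, 2.49 for Havcr2, 2.26 for Ramp3, 2.11 for Npy, 1.97 for the retinoic acid-binding Crabp2, 1.89 for Hilpda, 1.74 for Apbb3 and 1.71 for Mxi1.

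Interferon-response genes had a median of -1.62 in this comparison, at percentile 0, with 20 of 23 at least 2-fold lower. The list of MHC class I and antigen presentation, which shares members with the interferon list, was at -0.95, at percentile 0. Chemokines were at -0.49 and cytokines at -0.47, both at percentile 0, with 7 of 20 and 5 of 17 lower. Cholesterol and fatty acid genes were at 0.39, at percentile 100, with 1 of 17 higher. NF-κB genes were at -0.35 (percentile 0.01), matrix proteases at -0.31 (percentile 0.05) and targets of cAMP and CREB at -0.27 (percentile 0.04). Hyaluronan genes were at 0.09, with 0 of 8 past 2-fold. Macrophage markers were at -0.33, at percentile 0.01, with 1 of 23 lower. Matrix structural genes were at 0.13, at percentile 100, and at -0.01 as deposited. The median of cholesterol and fatty acid synthesis was 0.25 as deposited, and that of cAMP and CREB targets -0.41. As deposited, 44 of 7041 genes were at least 2-fold higher and 220 lower, or 16.7% higher. Relative to the median gene, which was dimmer by a log2 of -0.14, the counts were 68 and 167, or 28.9% higher.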

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

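Using ratios as deposited and taking the combined pattern relative to the median gene were chosen after the data were seen, and the other settings were fixed before. There is 1 array per group, so leaving out an array was not possible. No paired analysis was possible because each group has 1 array. Below, no floor stands for no floor and no filter on low values together. Trimmed mean and median scaling apply 1 factor per array, which drops out of ratios relative to the median gene except near the floor, so they say little about list medians or named genes and are left out of the totals. The scale as deposited adds 1 constant to all ratios of a comparison. Its totals therefore follow from the size of that constant against each SD or median. On that scale, 27 list medians moved by less than the SD of random lists, 73 by more, and 4 that lay outside the middle 95% of random lists changed sign. Under the other settings these numbers were 689, 141 and 2. Named ratios were checked if picked as highest or lowest, as bounds, as receptors and enzymes, or by the combined pattern. Ratios named only as list members were not checked. Of the ratios checked, 110 moved by less than the SD between probe sets and 32 by more as deposited, and 914 and 215 under the other settings. Among the ratios checked, none of at least 2-fold changed sign. Sign changes of smaller ratios and of medians inside the middle 95% were not counted. Counts below are listed only for settings that changed them by over 1.5-fold, so unlisted settings can differ by less. The correlation is listed where it moved by at least its SD over resampled genes. The iloprost ratio of IL-1β genes is listed where it moved by at least the SD of random lists. The cause of each change below was not tested.

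Genes higher with IL-1β (195) numbered 358 and 129 with floors at the 30th and 65th percentile, 124 with a pseudocount, 1551 with no floor, 111 with trimmed mean scaling, 115 with median scaling, 115 with quantile and 127 with loess normalization, 743 at 1.5-fold and 75 at 3-fold. Genes lower with IL-1β (11) numbered, in the same order, 66, 4, 4, 929, 42, 38, 38, 31, 77 and 1.

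Genes higher with indomethacin (9) numbered 53 with a floor at the 30th percentile, 3 with a pseudocount, 955 with no floor, 17 under each of the 4 scalings, 50 at 1.5-fold and 1 at 3-fold. Those lower (60) numbered 195 and 36 with the lower and higher floor, 1259 with no floor, 337 at 1.5-fold and 18 at 3-fold. The unlisted settings all gave fewer, from 40 with a pseudocount to 56 without cross-hybridising probe sets.

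Genes higher with iloprost against indomethacin (141) numbered 350 and 77 with the lower and higher floor, 1400 with no floor, 556 at 1.5-fold and 50 at 3-fold. Those lower (221) numbered 1288 with no floor, 489 at 1.5-fold and 91 at 3-fold. Against IL-1β alone, those higher (44) numbered 147 and 20 with the lower and higher floor, 18 with a pseudocount, 1096 with no floor, 74 with trimmed mean scaling, 200 at 1.5-fold and 10 at 3-fold. Those lower (220) numbered 332 with the lower floor, 1369 with no floor, 612 at 1.5-fold and 81 at 3-fold. Here too the unlisted settings all gave fewer, from 150 with trimmed mean scaling to 214 without cross-hybridising probe sets.

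The combined pattern (183) held for 422 and 84 genes with the lower and higher floor, 93 with a pseudocount, 1269 with no floor, 112 with trimmed mean, 121 with median scaling, 109 with quantile, 111 with loess, 43 at 2-fold and 119 relative to the median gene. Its opposite (33) held for 148 with the lower floor, 15 with a pseudocount, 709 with no floor, 64, 59, 63 and 66 under the 4 scalings, 8 at 2-fold and 60 relative to the median gene.

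The correlation of the IL-1β and iloprost ratios (0.19) was 0.15 and 0.22 with the lower and higher floor, 0.0367 with no floor, 0.21 with quantile and 0.21 with loess normalization. The iloprost ratio of IL-1β genes as deposited (0.32 over 195 genes) was 0.27 with the higher floor, 0.17 with no floor, 0.38 with trimmed mean, 0.45 with median scaling and 0.28 with loess normalization.

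As deposited, 4 list medians changed sign: matrix structural genes with IL-1β (0.14) and in the net comparison (-0.00623), MHC class I and antigen presentation genes with indomethacin (-0.0605) and macrophage markers with IL-1β (0.12). Bone and Wnt/BMP regulators with IL-1β were at -0.0316 with the higher floor, and adipocyte markers with iloprost at -0.14 with no floor.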

Other observations

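Protease inhibitors had medians of -0.04 with IL-1β, 0.03 with indomethacin and 0.06 with iloprost, although Serpinb2 was at -2.35 with iloprost. Growth and angiogenic factors had medians of 0.09, 0.08 and 0.08, with the vascular growth factor Vegfa at 1.81, -0.95 and 0.78. IGF genes were at 0.05, -0.03 and -0.03, with the insulin receptor substrate Irs1 at -1.41 with IL-1β and 1.13 with indomethacin. Complement genes were at -0.08, 0.04 and 0.13, and oxidative stress genes at 0.10, -0.06 and 0.09, with the cystine transporter Slc7a11 at 2.08 with IL-1β. With iloprost, adipocyte markers were at 0.44 over 3 genes that went both ways, with the lipase Lpl at -1.63, contractile genes at 0.07, and glucocorticoid and circadian genes at 0.21. The chondrocyte median over 2 genes was 0.16, and the endothelial list rested on Flt1 alone, at a bound of at most -0.69. No lymphocyte marker was above the floor on any array.

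For the patterns below, the test on macrophage markers was fixed before its value was seen. The other 6 tests, on control transcripts, the median gene, simulated arrays, arrays that are not shared and the genes chosen by iloprost, were chosen after the result, or a closely related value such as the correlation of the IL-1β and iloprost ratios, had been seen.

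The lower interferon-response genes with iloprost were set against fewer macrophages in that dish. Loss of cells would lower all markers of the cell type by about as much as the genes it explains, and the bound set for this was a log2 ratio of -0.93. The macrophage markers had a median of -0.24 over 23 genes, with a scaled median absolute deviation of 0.34, which argues against loss of macrophages as the whole cause. The markers moved apart, with Adgre1 at 1825 without and 1074 with iloprost and Aif1 at 403 and 242, against 1846 and 1905 for Tyrobp and 1618 and 1512 for Cd68. Since 18 of the 23 were lower and 5 higher, loss of some macrophages stays open. A dimmer array would lower all genes alike. The median ratio of 6416 genes was 0.0384 as deposited with a spread of 0.32, against a bound of -0.93, which argues against dimming as the whole cause. The quality of the RNA was not tested, and an effect of iloprost on interferon signalling remains a hypothesis. A change within macrophages or within fibroblasts, and a difference between single dishes that has nothing to do with iloprost, both stay open.

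The genes lower with indomethacin and higher with iloprost were set against noise of the array that both ratios share. Their count relative to the median gene, 119, lay above the highest of 1000 simulated sets even with the wider noise, 71. The iloprost ratio of genes chosen on the vehicle and IL-1β arrays had a median of 0.35 over 120 genes, above 0.09, the upper end of the middle 95% of random lists. The count rests on simulated noise and excludes nothing alone. The median of genes chosen without the indomethacin array argues against noise of that array as the whole cause, for genes higher with IL-1β. Only 49 of the 119 genes were at least 2-fold higher with IL-1β, so the median cannot decide the question for the others. The hypothesis that iloprost restores part of the IL-1β response that indomethacin removes is left open, since a fault of the 1 indomethacin dish would lower and restore the same genes and was not tested.

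The excess of higher over lower genes with IL-1β as deposited may come in part from a brighter array. Control transcripts added in fixed amounts were brighter on the IL-1β array by a median of 0.22 with a spread of 0.07, and the median gene by 0.23. On the other arrays the controls did not follow the median gene. They were at -0.05 against 0.08 with indomethacin and at -0.21 against 0.09 with iloprost, so how far brightness accounts for the shift stays open. With the shift taken off, 75.5% of the genes past 2-fold were still higher, so a shift of all genes alike does not account for all of the excess.

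If prostanoids made under IL-1β act on the genes that iloprost acts on, these genes should also differ between IL-1β and vehicle, on arrays that play no part in choosing them. The 223 genes at least 2-fold lower with iloprost had a median IL-1β ratio of -0.27. This lay below -0.04, the lower end of the middle 95% of random lists. Below the median gene were 171 of them, but only 10 were at least 2-fold lower with IL-1β, and 9 were at least 2-fold higher. Without the interferon list the median was -0.23 over 201 genes. As deposited, all IL-1β ratios are higher by 0.23, which is about the size of both medians. Random lists shift alike. With indomethacin against IL-1β alone, the interferon list had a median of 0.25, with 22 of 23 above the median gene. There 0 of 23 were past 2-fold, against a median of -1.87 and 22 of 23 lower with iloprost. These 2 comparisons share the indomethacin array. The 135 genes at least 2-fold higher with iloprost and measured in both comparisons had a median of 0.30, above 0.04. Of these, 97 were above the median gene, 34 at least 2-fold higher with IL-1β and 2 at least 2-fold lower. This is consistent with the hypothesis, but it reads the same relation as the correlation of 0.19 that was already known, and IL-1β could act on these genes without prostanoids.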
